A study of Homo sapiens with 7 samples.

How the data were processed

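RNA of the prostate cancer line PC3 was compared on 7 2-colour cDNA arrays. Per the labels, cells were kept for 10 h with or without 100 ug/ml emetine, an inhibitor of translation, and then received 5 ug/ml actinomycin D, which stops transcription. Cells were collected 0, 10 and 30 min and 1, 2 and 4 h later, with 1 array per time that set emetine-treated against untreated RNA, and 1 further array set treated RNA against itself. The description of the 0 min array names another prostate line, LNCaP, and a hybridisation of treated against treated RNA, while its channel names give PC3, treated and untreated. It was analysed by its channel names.

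The deposited values are log2 values of the ratio of the 2 channels. Per the labels' descriptions, the authors divided mean intensities after subtracting background, normalized each slide on housekeeping genes with a ratio statistics method, and discarded ratios of low quality from their later work. The base of the logarithm is not stated. It was taken from the values: 99.8% of them are the base 2 logarithm of a whole multiple of 0.0001 (tolerance 0.05 of that unit), against 10.7% for the natural base and 9.87% for base 10. The array medians lay between 0.01 and 0.05. Neither the housekeeping genes used nor the quality values are in the table, and signal over background is not known. The number of arrays limits the precision.

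Which channel is on top of the ratio is not settled by the labels. They assign Cy5 to untreated and Cy3 to treated RNA and also speak of sample over reference. Signs are therefore given as deposited, as positive and negative ratios. That a positive ratio means more RNA after emetine is likely but not established. Its basis is a prediction made with the design, that immediate early genes rise when translation is blocked. Because each slide was normalized, more RNA here means more relative to the other RNA on the slide, not more in total.

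On each array 1 value stood on 179 to 328 of the 15488 rows, where the next most frequent value stood on at most 11. These repeats were set to missing, a choice made after seeing the data.

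Gene names rest on an alignment found by search on these data. The platform annotation gives 1 symbol for 11966 probes, several for 464, and does not list 3058. Matched by identifier as deposited, pairs of probes with the same accession had a Pearson correlation of 0.05 across 1478 pairs. With each run of 440 annotation entries placed at the start of a block of 484 rows (32 blocks of 22 by 22 spots), it was 0.653 across 1481 pairs and 0.877 across 474 pairs of repeated control accessions. In 1000 shuffles of the pairs the highest was 0.08. In all, 24 layouts were compared, 1 of them the same as the one used under another name, and the highest of the others gave 0.06 for the accessions that are not controls. The control pairs do not single out the layout, since they gave 0.877 and 0.801 under others that place the annotation in lines of 20. A search of 3001 offsets of the whole table gave at most 0.09. A search of 33011 offsets in 11 windows gave at most 0.633, in the window from row 1 (73 pairs), where the first block needs no shift. Of 44 placements of the remaining annotation entries none was used (highest 0.316), and 4 limits on the named positions were considered. In 32 of 32 blocks the pairs were most alike without a shift among 121 shifts. Only the first 372 positions of each run were considered for names. Among testable groups of 12 positions there, 29 had their highest correlation unshifted, and group 17 (positions 193 to 204, rho 0.127 over 27 pairs) did not and was left unnamed after that was seen, so 360 positions per run were named. Of the groups beyond that limit, groups 32 and 35 were highest unshifted (0.356 and 0.508), and groups 33 (0.309 against 0.345) and 34 (0.478 against 0.552) were higher with a shift. The criterion was the likeness of probes of one accession, but values of named genes had been seen under both pairings before it was fixed. A name thus depends on a row's place in its block and not on its deposited identifier. This left 9424 named rows for 7653 genes and 6064 unnamed rows. Of 1410 genes with at least 2 probes, 36 had probes on opposite sides beyond 0.5. The alignment step was tested on simulated data and found 3 of 3 simulated layouts.

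Probes of a gene were averaged, and unnamed rows were kept as they were. A gene or row needed a value on at least 5 of the 6 time course arrays, which left 13370, of which 7621 were named genes. Two-sided tests were run with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p: the mean log2 ratio of the 6 arrays against 0, and the slope in log2 per hour. Time points served as replicates, since no time has a second array. The p-values measure only the spread between these arrays, which come from 1 experiment as far as the labels say. Of 24 gene lists, 23 had members and were tested with limma's camera (preset correlation 0.01, lists of at least 5 members), and again with an estimated correlation. Camera compares a list with the other genes. Fry, also run, tests a list against 0, so its calls answer another question. The mitochondrially encoded list had 0 members, and 1 tested list, which counts of lists include, and some single genes fixed in advance are not reported here. Correlations between arrays are across genes, which are not independent replicates, and carry no p-value. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 prepared the tables.

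The tests, the gene lists, the rule for named genes and most other settings tried were fixed before the data were examined. The rule took, for the mean, the 12 highest and 12 lowest genes among those that passed with the same sign on every array; for the slope, the 8 highest and 8 lowest that passed, or the 8 of each sign with the smallest p if fewer than 5 passed; the 3 members of each list with the smallest p; and a fixed set of single genes. Other list members named are examples chosen after their values were seen.

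On simulated data with 13370 genes, the mean test recovered 46.3%, 86.6% and 100% of genes shifted by 0.5, 1 and 2 (log2), with 6 false calls. The slope test recovered 4.48%, 55.2% and 97.0% of genes with slopes of 0.25, 0.5 and 1 (log2 per hour), with 2 false calls. Camera called a list shifted by 1 and 0 of 22 other lists in its own simulation. All simulated values were independent between genes and arrays, so these simulations cannot show false calls that arise from correlated genes. Estimated correlations of the lists in the mean test ran from -0.04 (luminal prostate genes) to 0.51 (oxidative phosphorylation), against the preset 0.01. The glycolysis list, at -0.00848, lay below the preset and still lost its call with the estimate. The loss of calls is therefore not due to correlated genes alone. Alternatives covered centring and scaling of arrays, missing values, subtraction of the self against self ratio, probes kept apart, other tests, thresholds and time scales, and leaving out each array. Alternatives chosen after seeing the data kept the repeated value, changed which positions were named, matched names by identifier as deposited, or centred each block.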

Results

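The series measured RNA in PC3, a line derived from a prostate cancer metastasis that grows without androgen, at 6 times after actinomycin D, with emetine-treated and untreated cells on the same array. Each time had 1 array, and 1 self against self array measured the spread without a difference between the cells. The table held 15488 rows per array. Blocking translation also blocks nonsense-mediated decay (NMD), the pathway that removes transcripts with a premature stop codon, so the design asks which transcripts accumulate under emetine and how the ratio moves once transcription is stopped. Gene names below rest on an alignment of rows to the annotation that was found by search on these data. Under names matched by identifier as deposited, 1632 of 4783 calls among named genes were kept with the same sign and 2301 changed sign. Signs are given as deposited: a positive ratio likely, but not certainly, means more RNA after emetine. More is meant relative to the other RNA on the slide, since each slide had been normalized. A change in total RNA cannot be seen in these ratios.

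The first comparison set treated against untreated RNA over the 6 arrays. The highest mean ratio belonged to GADD45B, a stress-induced regulator of kinase signalling, at 5.39 ± 0.49 (log2, SD, n = 6), a 42.0-fold ratio. TNFAIP3, a feedback inhibitor of NF-kB, followed at 5.16 ± 0.65, the chemokine CXCL8 at 5.00 ± 0.58 and the transcription factor KLF10 at 4.88 ± 0.56. At the other end, LPCAT1, an enzyme of phospholipid remodelling, stood at -3.57 ± 0.16, an 11.9-fold ratio, and TTL, the tubulin tyrosine ligase, at -3.04 ± 0.67. All of these had the same sign on 6 of 6 arrays, which the rule for naming them required.

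Other genes with high positive ratios were AMOTL2 at 4.82 ± 0.54, TNFAIP2 at 4.75 ± 0.43, the ligand-activated transcription factor AHR at 4.60 ± 0.92, and the kinase PLK2 at 4.51 ± 0.52. TGDS (4.46 ± 0.49), the ephrin ligand EFNA1 (4.44 ± 0.52), and the small GTPases GEM (4.43 ± 0.65) and RND1 (4.41 ± 0.74) completed the 12 highest. Among the lowest, MAT2A, which makes S-adenosylmethionine, had a mean of -2.93 ± 0.31, the ribosomal protein gene RPS21 -2.77 ± 0.17 and PCP4 -2.76 ± 0.56. NT5DC2 (-2.75 ± 0.27), the tubulin gene TUBA3C (-2.68 ± 0.15) and the amino acid transporter SLC7A5 (-2.66 ± 0.29) came next. The probes of SLC7A5 stood at -3.19 and -2.14. The lipid transporter ABCA3 (-2.61 ± 0.46), the phosphatase PTPRU (-2.55 ± 0.38), the kinase CAMKK2 (-2.54 ± 0.36) and ALDH1A3, a retinoic acid synthesis enzyme (-2.48 ± 0.26), completed the 12 lowest. On the self against self array the 24 genes lay between -0.49 (RPS21) and 0.69 (AHR).

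Of 13370 genes and unnamed rows tested with limma, 4607 had a positive and 3835 a negative mean ratio at the threshold, 63.1% in all. Among the 7621 named genes these were 2727 and 2149. A mean of at least 1 in size was reached by 1539 positive and 789 negative ones, 933 and 400 of them named genes. The split by sign depends on where the normalization set 0. With each array centred on its median there were 4325 positive and 4146 negative calls. With the self against self ratio subtracted there were 3975 positive and 4140 negative calls, and of 4876 calls among named genes 4026 were kept with the same sign and 164 changed sign. The adjusted p was 1.12e-07 for GADD45B and 7.87e-08 for LPCAT1. In the first block of the array, where the names need no shift, 314 genes were tested, with 123 positive and 76 negative calls that included CXCL8 at 5.00 and IL6 at 3.96.

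**Figure D1:**
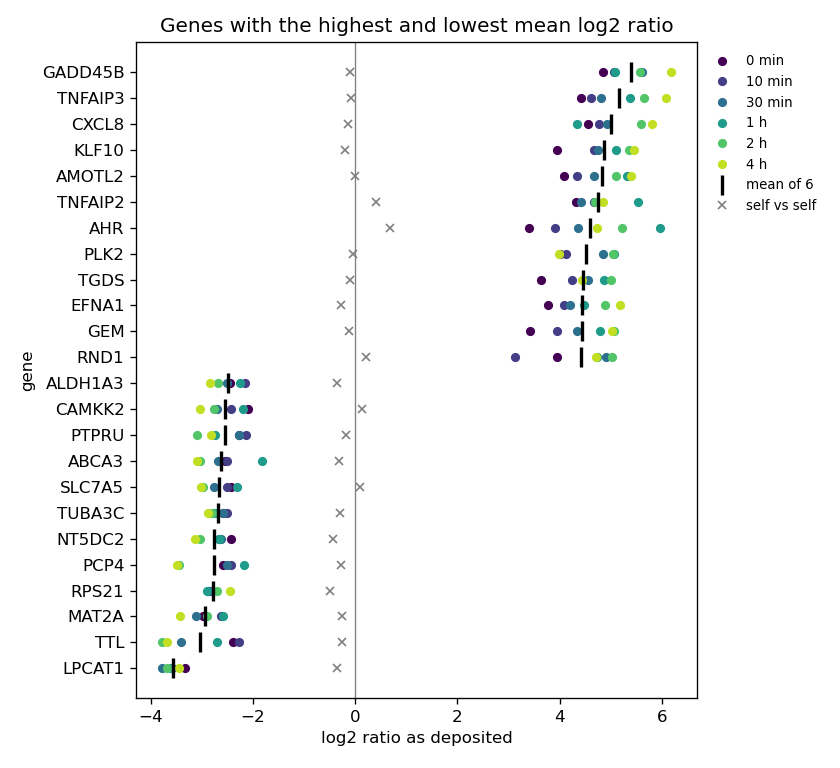
Log2 ratio as deposited (x axis) of the 12 genes with the highest and the 12 with the lowest mean ratio, with 1 point per array coloured by time, a bar at the mean of the 6 arrays and a cross for the self against self array. GADD45B has the highest mean, 5.39, and LPCAT1 the lowest, -3.57.

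Genes of NF-kB and cytokine signalling had mostly positive ratios. Of 31 members, 27 were called positive, 2 negative and 2 did not pass, also when adjusted over the list alone, with a median of 2.55. They included the adhesion gene ICAM1 (4.19 ± 0.29), the protease PLAU (2.93 ± 0.20), IL6 (3.96), CCL2 (3.94) and NFKBIA, the inhibitor that NF-kB itself induces (3.28). By camera, the list had an adjusted p of 2.52e-09, and adjusted p = 0.401 with an estimated correlation.

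Immediate early genes, which respond to stimuli without new protein, followed. Of 40 members, 28 were called positive, 4 negative and 8 did not pass (28 and 5 adjusted over the list alone), with a median of 1.14. ATF3 stood at 4.38 ± 0.40, SNAI2 at 4.14, CCN1 at 3.50 ± 0.38 and JUNB at 3.24, while JUND stood at -1.44 and SRF at -0.99. Camera gave an adjusted p of 1.57e-05, and adjusted p = 0.401 with an estimated correlation. This direction is the basis for reading a positive ratio as more RNA after emetine.

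Among transcripts known as NMD targets, 16 of 28 were called positive, 6 negative and 6 did not pass, with the same counts adjusted over the list alone and a median of 0.70. The positive ones included GADD45B, ATF3, the stress factor gene DDIT3 (2.12 ± 0.22), MAP3K14 (3.35) and the splicing regulator SRSF3 (1.68 ± 0.23), and the negative ones GADD45A, HNRNPDL (-0.74) and SMG5 (-0.71). The list passed camera with an adjusted p of 0.0115, and adjusted p = 0.401 with an estimated correlation. ATF3, DDIT3 and ATF4 also belong to the integrated stress response list, and ATF3 to the immediate early list. SRSF3, CLK1 and HNRNPDL are also splicing factors in their list, and UPF2 is in the NMD machinery list. The shift of the NMD list is therefore not separate from those of the other lists.

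Replication-dependent histone genes, whose transcripts end without a poly(A) tail, had a median of 2.79. Of 12 members, 9 were called positive and 3 negative, also adjusted over the list alone. H2AC6 stood at 3.67 ± 0.24, H2BC15 at 3.62 ± 0.35 and H2BC7 at 3.56 ± 0.27, and the lowest, H2BC21, at -0.62. By camera, the list had an adjusted p of 0.00331, and adjusted p = 0.401 with an estimated correlation. Histone genes are near copies of each other, so a cDNA probe may bind several, and single members are uncertain.

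Zinc finger genes of the ZNF series had 65 of 101 members called positive, 9 negative and 27 not passing, the same adjusted over the list alone, with a median of 0.61. ZNF136 stood at 2.75 ± 0.50, ZNF75D at 2.41 ± 0.38 and ZNF224 at 1.95 ± 0.20. Camera gave an adjusted p of 3.16e-05, and adjusted p = 0.401 with an estimated correlation.

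Cytosolic ribosomal protein genes were mostly negative. Of 52 members, 33 were called negative, 5 positive and 14 did not pass, the same adjusted over the list alone, with a median of -0.63. RPS21 and RPL26 (-1.54 ± 0.29) were among the lowest, whereas RPL28 stood at 2.50 ± 0.52 and RPS12 at 1.69. The list passed camera with an adjusted p of 2.83e-04, and adjusted p = 0.576 with an estimated correlation. The median was -1.39 on the 1 h array and -0.40 for the mean without that array. At 0 min the median was -0.09, and on the arrays after 0 min it ran from -1.39 at 1 h to -0.26 at 30 min. Ribosomal protein genes have many processed copies, so single members are uncertain.

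Nuclear genes of oxidative phosphorylation had 30 of 64 members called negative, 4 positive and 30 not passing (29 and 3 adjusted over the list alone), with a median of -0.40. NDUFV1 of complex I stood at -1.18 ± 0.23, ATP5F1B of the ATP synthase at -1.15 ± 0.21 and UQCRC1 of complex III at -0.997 ± 0.217. On the self against self array these genes stood at -0.44, -0.52 and -0.27, while the median of the list was 0.01. By camera, the list had an adjusted p of 1.19e-04, and adjusted p = 0.592 with an estimated correlation. The median was -1.29 on the 1 h array, and the median of the mean ratio was -0.22 without that array. At 0 min the median was 0.01, so the list was not shifted there. On the arrays after 0 min it ran from -1.29 at 1 h to -0.27 at 30 min.

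Cytoskeletal and other housekeeping genes had 16 of 23 members called negative, 3 positive and 4 not passing, the same adjusted over the list alone, with a median of -0.61. TUBA1A stood at -1.92 ± 0.27, ACTB at -1.71 ± 0.24 and TUBB4B at -1.57 ± 0.22, while TBP, a general transcription factor, stood at 1.17. Camera gave an adjusted p of 4.30e-04, and adjusted p = 0.401 with an estimated correlation. On the self against self array TUBA1A stood at -0.79, ACTB at -0.51 and TUBB4B at -0.12, and the median of the list was -0.16. With that array subtracted the median of the list was -0.34 (camera adjusted p = 0.0121). The median on the 1 h array was -1.24. The slides had been normalized on housekeeping genes that the labels do not name. The probes for TUBA1A stood between -2.54 and -0.87, and tubulin genes are near copies of each other.

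Of 23 genes of glycolysis and hypoxia, 14 were called negative, 3 positive and 6 did not pass, the same adjusted over the list alone, with a median of -0.51. The glycolytic enzymes HK2 (-1.13 ± 0.18) and ENO1 (-0.79 ± 0.17) were negative, and the secreted peptide gene ADM was positive (3.27 ± 0.41). On the self against self array ENO1 stood at -0.49, HK2 at -0.25 and ADM at 0.31. The list passed camera with an adjusted p of 0.0121, and adjusted p = 0.401 with an estimated correlation. That estimate was -0.00848, below the preset 0.01, so a higher correlation is not what ended the call. With the self against self ratio subtracted, the list did not pass (median -0.18, adjusted p = 0.288).

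Genes of the integrated stress response split. Of 25, 8 were called positive, 8 negative and 9 did not pass, the same adjusted over the list alone. ATF3, DDIT3, CEBPB (2.34), ATF4 (2.06), SLC3A2 (1.34) and CARS1 (1.01) were among the positive ones, and SLC7A5, SHMT2 (-0.78), MTHFD2 (-0.60) and PHGDH (-0.60) among the negative ones. Camera gave an adjusted p of 0.870, with a median of -0.11 and a mean of 0.29, while fry, which tests against 0, called the list positive (adjusted p = 0.00615). The NMD machinery had 5 positive, 5 negative and 5 members not passing, the same adjusted over the list alone (camera adjusted p = 0.871, median -0.09, mean 0.10, positive by fry with adjusted p = 0.0153). UPF2 stood at 1.37 ± 0.30, the decapping factor DCP1A at 1.14 ± 0.32 and the exonuclease XRN1 at 1.15 ± 0.32. Splicing factors had 19 positive, 12 negative and 14 not passing among 45, the same adjusted over the list alone (camera adjusted p = 0.727, median 0.14, positive by fry with adjusted p = 0.00842). HNRNPAB at -1.63 ± 0.14 and SNRPA at -1.16 ± 0.14 contrasted with SRSF3.

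Among single genes fixed in advance, the cell cycle inhibitor CDKN1A stood at 3.34 ± 0.65, JUN at 2.81 ± 0.88, MCL1, an apoptosis inhibitor with a short-lived transcript, at 2.49 ± 0.90 and IER3 at 1.68 ± 0.18. GADD45A, a reported NMD target, stood at -0.34 ± 0.10 (limma adjusted p = 0.00364). It has 1 probe, which stood at -0.14 on the self against self array, where the 1st percentile was -0.55. UPF1, the NMD helicase, stood at -0.25 ± 0.18 (limma adjusted p = 0.0361) and did not pass when the 0, 10 or 30 min, 2 h or 4 h array was left out, with means from -0.26 to -0.20. MYC did not pass (0.02 ± 0.78, limma adjusted p = 0.956), with ratios from -1.30 at 0 min to 0.67 at 2 h. EPHB2 was not analysed here, since no named row carried it.

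The share of genes and unnamed rows with a 2-fold or larger ratio was compared with the self against self array, time by time and with no test. On the self against self array 0.857% had a ratio of at least 1 and 0.155% of at most -1 (log2). These shares were 8.24% and 4.69% at 0 min, 9.81% and 4.49% at 10 min, and 11.1% and 5.73% at 30 min. They were 15.1% and 10.4% at 1 h, 14.3% and 8.70% at 2 h, and 15.0% and 9.38% at 4 h. Between 24.6% (0 min) and 38.1% (1 h) lay outside the 1st to 99th percentile of the self against self array. With the repeated value kept these were 10.97% and 23.45%. The 1st percentile of the self against self array was then -1.34, the repeated value of that array, against -0.55. At 0 min 264 genes and unnamed rows lay below it, against 2071. Above the 99th percentile lay 1241, against 1227, so the drop came from the moved limit.

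**Figure D2:**
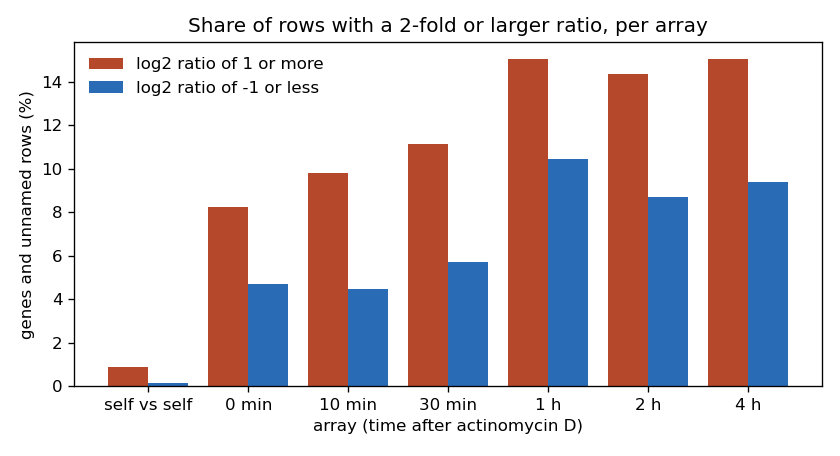
Percent of genes and unnamed rows (y axis) with a log2 ratio of at least 1 or at most -1 on each array (x axis). The self against self array has 0.857% and 0.155%, and the time course arrays have between 8.24% and 15.1% positive.

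The slope comparison asked how the ratio moved after transcription stopped. DKK1, a secreted Wnt inhibitor, was the only gene or unnamed row called by limma. Its slope was 0.72 ± 0.05 (log2 per hour, SE, n = 6, adjusted p = 0.0199), from -0.32 at 0 min to 1.37 at 2 h and 2.64 at 4 h. The call of DKK1 was lost when the 0, 10 or 30 min, 2 h or 4 h array was left out (slopes from 0.70 to 0.80) and kept without the 1 h array. It was also lost with arrays scaled to one spread (slope 0.63) or with the order of the times in place of hours. No gene or unnamed row was called with a negative slope.

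The genes with the next smallest p did not pass. The calcium channel TRPV6 had a slope of 0.49 (limma adjusted p = 0.0852), MAD2L1BP 0.44, the polyadenylation factor CSTF1 0.46 and ALKBH1 0.57. The death domain adaptor FADD had 0.51, the kinase PIM1 0.50 and the adaptor GRB10 0.44. On the negative side, F2RL2 had -0.41 (limma adjusted p = 0.117), ECEL1 -0.43, SEC16A -1.12, NIT2 -0.34, AGO1 of the RNA silencing machinery -1.29, FBXO7 -0.47, FAM20B -0.30 and the E2F partner TFDP1 -0.29. Without the 4 h array these 8 slopes were -0.26 for F2RL2, -0.15 for ECEL1, -0.16 for SEC16A, -0.36 for NIT2, 0.0428 for AGO1, -0.0349 for FBXO7, -0.18 for FAM20B and -0.46 for TFDP1, none of them called. At an unadjusted p under 0.05 there were 993 positive and 483 negative slopes. Without the 1 h array, limma called 93 positive and 6 negative slopes.

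As groups, immediate early genes (median slope 0.14, camera adjusted p = 2.87e-06), NF-kB and cytokine genes (0.16, adjusted p = 7.56e-06) and ZNF genes (0.06, adjusted p = 0.00186) had higher slopes than other genes. With an estimated correlation the values were adjusted p = 0.376, adjusted p = 0.376 and adjusted p = 0.686. Tested by fry against a slope of 0, and not against other genes, the lists did not pass (adjusted p = 0.0504, 0.0504 and 0.223). No member of these lists was called over all genes, and adjusted over the list alone 7 of 40, 5 of 31 and 2 of 101 had a positive slope and 0 a negative one. Scaling the arrays to one spread ended all of these calls (adjusted p = 0.441, 0.279 and 0.441) and turned the median slope of the NF-kB genes to -0.04. Without the 4 h array the median slope of the ZNF genes was 0.14, and 4 lists were called lower: oxidative phosphorylation (adjusted p = 2.48e-05), proteasome, housekeeping and translation factor genes. Over the 6 times, the median of the NF-kB genes was 2.09, 2.38, 2.46, 2.63, 2.66 and 2.76, and that of the immediate early genes 1.11, 0.88, 1.38, 1.24, 1.35 and 1.64.

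**Figure D3:**
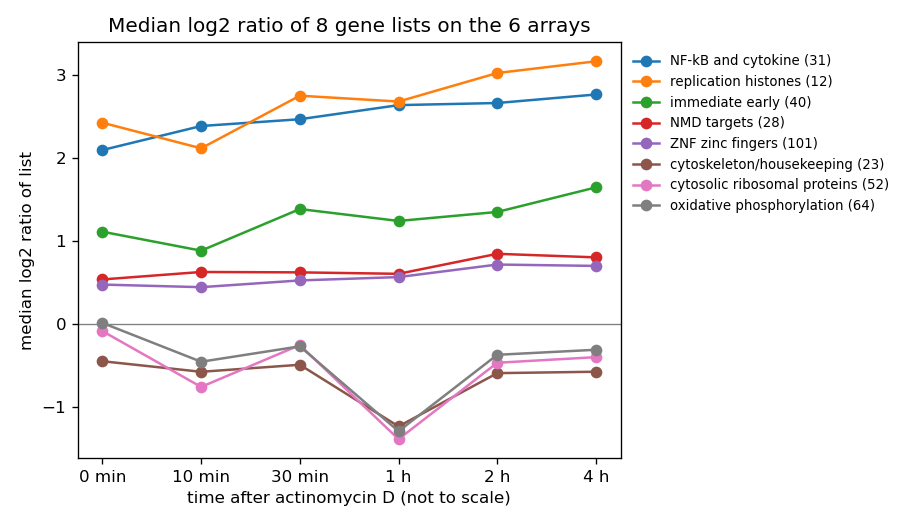
Median log2 ratio (y axis) of 8 gene lists on each time course array (x axis, times not to scale), with the number of members in brackets. The NF-kB list moves from 2.09 at 0 min to 2.76 at 4 h, and the ribosomal protein, oxidative phosphorylation and housekeeping lists lie lowest on the 1 h array.

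Arrays were also compared across genes. All 6 time course arrays correlated with each other, from a Pearson r of 0.731 (0 min and 1 h) to 0.916 (30 min and 2 h), and with the self against self array from 0.207 to 0.378. The 1 h array had the lowest mean correlation with the other 5, 0.796, and the 0 min array the next lowest, 0.844, against 0.862 to 0.883 for the rest.

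**Figure D4:**
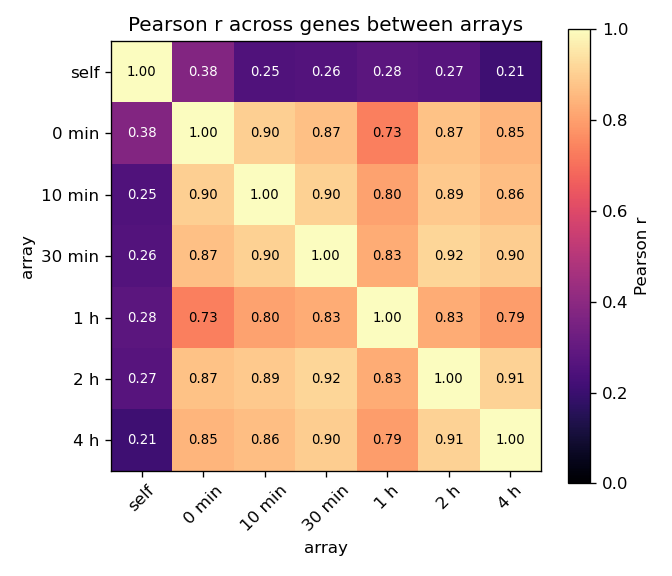
Pearson correlation across genes between each pair of the 7 arrays, by colour and number. Values between time course arrays range from 0.731 to 0.916, and those with the self against self array from 0.207 to 0.378.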

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

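The tests on the 1 h array were chosen after the result was seen; the others in this part were written with the design. Of 132 sets of 6 values examined (list medians, named genes and summaries of each array), 12 had 1 array far from the other 5. The 4 h array was the distant one in 6 of them and the 1 h array in 4. Chance gives about 1 in 20 for independent sets not chosen by their values. These sets overlap. Some of the genes were named for a negative slope, which favours a low 4 h value. The 12 can therefore not be set against chance.

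On the 1 h array the medians of proteasome genes (-0.59), oxidative phosphorylation genes (-1.29) and housekeeping genes (-1.24) lay far below the other 5 arrays. ADM lay above them on the same array at 4.07. On the 4 h array F2RL2 (-1.42), ECEL1 (-1.61), SEC16A (-5.62), AGO1 (-5.04) and FBXO7 (-1.96) lay below the other arrays, and MRPS12 (-0.79) lay above. The first 5 of these were named for a negative slope, a choice that favours genes low at 4 h. ZNF224 lay high at 2 h (2.33), and the median of immune and endothelial markers lay high at 0 min (0.12).

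The first pattern is the 1 h array, on which ribosomal protein and oxidative phosphorylation genes lay lower together than at 30 min and 2 h. Over the 116 genes, the 1 h ratio differed from the lower of the 2 neighbouring times by a median of -0.84 (quartiles -1.22 to -0.21). Bias between print blocks as the whole cause is argued against: block medians on this array ran from -0.17 to 0.25, and with each block centred the median difference was -0.78 (quartiles -1.22 to -0.21). Whether the ratios followed time cannot be told apart from a fault of this array, since the -0.84 comes from lists chosen for being low at 1 h. A difference in that hybridisation or in one of its RNA samples may remain as an explanation, and a brief change in the cells stays open, because no second array exists at 1 h.

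The second pattern is the description of the 0 min array, which speaks of LNCaP cells and of treated against treated RNA. The SD of its ratios was 2.54 times that of the self against self array and its correlation with the 10 min array was 0.900, which argues against a self hybridisation. Its mean correlation with the other 5 arrays was 0.844, above the lowest of the others, 0.796. That lowest value belongs to the doubted 1 h array; the excess is under the SD of the 0 min array's own correlations (0.066), and without the 1 h array the 0 min array was the lowest at 0.872, so LNCaP and PC3 RNA cannot be told apart there. The reading of this test as open, and not as evidence against LNCaP, was made after its value was seen.

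The third pattern is the sign of the ratio. The median of the immediate early list was 1.14 against 0.04 for all genes (camera adjusted p = 1.57e-05, and adjusted p = 0.401 with an estimated correlation), the side predicted if treated RNA is on top. The ratio is therefore likely treated over untreated, although Cy5 over Cy3 with the dyes as labelled would be the reverse. The test rests on the alignment of names: by identifier as deposited the list median was 0.13 (adjusted p = 0.943).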

How the results depend on the processing

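The alternatives that kept the repeated value, changed which positions were named, matched names by identifier as deposited or centred each block were chosen after seeing the data. Each time course array sets treated against untreated RNA of the same time, so its ratio is already a paired comparison. No pairing between arrays was possible because the self against self array shares no comparison with the time course and each time has 1 array. Signal over background is not in the table, so what weak spots limit is not known. Of counts and correlations, 181 stayed within their bounds and 36 did not. Of values for named genes outside the identifier matching, 2451 kept their direction and side of the threshold, 38 newly passed, 20 no longer passed and 1 reversed; for single lists these were 825, 12, 27 and 10 with the identifier matching included. Unless said otherwise, the cause was not tested.

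For treated against untreated, the stricter threshold (mean of at least 0.6 in size) gave 2746 positive and 2066 negative, by construction; leaving out 1 array gave 4117 to 4774 positive and 3412 to 4028 negative. For the slope, positive calls numbered 0 with arrays scaled to one spread, 0 with the order of times, 0 for late against early times, 3 with trend and robust settings, and 0 to 93 with 1 array left out, 93 being without the 1 h array. Negative slope calls were 0 to 6 with 1 array left out, 6 also being without the 1 h array, and an unadjusted p under 0.01 gave 348 positive and 82 negative. In limma's fit over all arrays, 993 positive and 483 negative slopes had an unadjusted p under 0.05.

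For lists in the mean test, camera with an estimated correlation called 0 higher and 0 lower than other genes, and names by identifier as deposited 0 and 0, against 6 and 4. Fry, which tests against 0, called 10 positive and 8 negative. Those that camera did not call included splicing factors and apoptosis regulators on the positive side. On the negative side they included cell cycle, heat shock, sterol and lipid synthesis, and translation factor genes. For slopes, 3 lists were called higher, and 0 with scaling to one spread, 0 with an estimated correlation and 0 with names by identifier; fry called 1 positive against 0, the apoptosis regulators, which is none of the 3; with 1 array left out 0 to 4 were called lower, the 4 being without the 4 h array. By identifier, camera's direction against other genes reversed for some lists, without a call (adjusted p = 0.943, and 0.994 for the ZNF slope). Their medians changed sign for ribosomal proteins (0.21), ZNF genes (-0.0817, slope -0.0116) and housekeeping (0.0300). The medians of NMD targets (0.00105) and glycolysis (-0.00917) kept their sign but lay near 0. Fry called the integrated stress response (median -0.11) and the NMD machinery (-0.0893) positive against 0, where camera placed them below other genes without a call. Scaling turned the NF-kB slope (-0.0402), and the proteasome slope ran from -0.133 to 0.0434 with 1 array left out, the lowest being without the 4 h array.

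Per array, ratios of at least 0.6 in size numbered 557 for self against self and 4203, 4410, 4846, 5959, 5865 and 6054 over the 6 times. At a size of at least 1, keeping the repeated value gave 311 for self against self (116 positive and 195 negative). With that value set to missing there were 116 positive and 21 negative. The Spearman mean of the 1 h array was 0.744. Without 1 array the mean of AGO1 ran from -0.72 to 0.45, the highest being without the 4 h array.

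Named genes reversed by identifier as deposited had these means: TNFAIP3 -0.29, AMOTL2 -1.01, TNFAIP2 -0.55, AHR -0.37, TGDS -0.0294, EFNA1 -0.17, LPCAT1 0.0114, NT5DC2 1.05, ABCA3 0.18, ALDH1A3 0.0353, DKK1 -0.68, ALKBH1 -0.88, PIM1 -0.0222, ECEL1 0.31, SEC16A 0.0804, NIT2 0.52, AGO1 0.88, TFDP1 0.0283, ATF3 -0.79, CCN1 -0.47, ICAM1 -0.81, HNRNPAB 0.24, UPF2 -0.0429, DCP1A -0.16, XRN1 -0.27, RPL28 -0.15, RPL26 0.22, RRM2 0.15, KIF11 -0.27, BIRC5 0.0616, PMAIP1 -1.33, HSPA8 0.76, CCT3 0.31, PSMD8 0.24, ATP5F1B 1.09, SCD 0.38, ZNF75D -0.56, ZNF136 -0.0711, ENO1 0.57, ACTB 0.0447, EIF3B 1.255, AZGP1 -0.83, FKBP5 0.50, ACTA2 0.53, FN1 -1.73, CD68 0.50, CD14 -0.29, HLA-DRA 0.72, GADD45A 0.33, JUN -0.51, UPF1 0.0717 and DKK1 -0.12 for its slope.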

Other observations

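None of the tests in this part was chosen after the result was seen. Apoptosis regulators moved both ways: of 25, 13 were called positive, 7 negative and 5 did not pass, the same adjusted over the list alone, with a median of 0.29 (camera adjusted p = 0.406). The inhibitor BIRC2 (2.58 ± 0.36) and the death receptor FAS (1.66) were positive, and the survival genes BIRC5 (-1.47 ± 0.28) and BCL2L2 (-1.64) were negative. On the self against self array BIRC5 stood at -0.59 and BIRC2 at -0.13. Cell cycle genes had 21 of 49 called negative, 12 positive and 16 not passing (22 and 12 adjusted over the list alone), with a median of -0.19 (camera adjusted p = 0.110). RRM2 (-1.74 ± 0.26), PCNA (-1.18) and CDC20 (-0.44) were negative, and KIF11 (1.35 ± 0.17) and AURKA (1.33) positive.

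Translation factors had 14 of 36 called negative, 6 positive and 16 not passing, the same adjusted over the list alone (camera adjusted p = 0.134, median -0.15), with EIF4EBP1 at -1.17 ± 0.26, EIF3B at -1.07 ± 0.25 and EIF5B at 1.41 ± 0.41. EIF5B stood at 0.99 on the self against self array. Heat shock genes had 9 of 27 negative, 5 positive and 13 not passing (8 and 5 adjusted over the list alone; camera adjusted p = 0.184, median -0.15), with HSPA8 at -1.89 ± 0.20, CCT3 at -1.19 ± 0.24 and HSPA4 at 0.77 ± 0.08. Proteasome genes had 11 of 33 negative, 8 positive and 14 not passing, the same adjusted over the list alone (camera adjusted p = 0.228, median -0.13), with PSME3 at -1.29 ± 0.25, PSMD8 at -1.11 ± 0.20 and PSMD2 at -1.06 ± 0.16. On the self against self array PSMD2 stood at -0.45, PSME3 at -0.19 and PSMD8 at 0.20. Sterol and lipid synthesis genes had 10 of 21 negative, 4 positive and 7 not passing, the same adjusted over the list alone (camera adjusted p = 0.211, median -0.25), with the desaturase SCD at -1.79 ± 0.28, DHCR7 at 1.01 ± 0.21 and HSD17B7 at 0.88 ± 0.36. The probes of SCD stood between -2.50 and -0.40.

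Mitochondrial ribosomal proteins had 9 of 28 positive, 9 negative and 10 not passing, the same adjusted over the list alone (camera adjusted p = 0.779, median -0.13, mean 0.02), with MRPS31 at 1.55 ± 0.41, MRPS7 at 1.44 ± 0.22 and MRPS12 at -1.11 ± 0.16. Luminal prostate genes had 3 of 11 positive, 5 negative and 3 not passing (4 and 5 adjusted over the list alone; camera adjusted p = 0.779, lower, median 0.06), with AZGP1 at 1.13 ± 0.18, STEAP1 at -0.92 ± 0.46 and FKBP5 at -0.46 ± 0.20. Fibroblast markers had 4 of 14 positive, 3 negative and 7 not passing (3 and 3 adjusted over the list alone; camera adjusted p = 0.779, median 0.11, mean -0.01), with FN1 at 1.74 ± 0.25, ACTA2 at -1.61 ± 0.21 and COL1A2 at -0.85 ± 0.16. Immune and endothelial markers had 3 of 12 positive, 4 negative and 5 not passing, the same adjusted over the list alone (camera adjusted p = 0.561, median -0.15), with CD14 at 0.71 ± 0.32, CD68 at -0.92 ± 0.38 and HLA-DRA at -0.40 ± 0.11.

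Turning the sign of random arrays tested the 8442 calls for treated against untreated against chance: 1 of 32 sign patterns, the real one, gave as many, and the highest of the others was 0. The time course arrays correlated with each other (Pearson r from 0.731 to 0.916), so turning any of them was bound to lower the count. The result shows only that the ratios shared a sign across these arrays. It says nothing of the source of that shared sign, whether emetine, the dyes or the cultures. Of 100 orders of the times, 8 gave at least as many slope calls as the 1 of the real order, and the highest of the others gave 303, so chance is not excluded. An order that calls several times the real count points to a structure of the arrays, which was not tested. The orders that called 303, 265 and 16 gave the 1 h array the 4 h time, as did 14 others that called 0.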
